A study of Mus musculus with 6 samples.

How the data were processed

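Heart samples of male mice, 6 in all, 3 labelled ground control (GC) and 3 labelled partial gravity (PG), were profiled by sequencing ribosome-protected fragments. Per the labels' protocols, frozen hearts were lysed, nuclei, debris and mitochondria were spun out, extracts were digested with RNase I, monosomes were collected through 50% sucrose and fragments of 25 to 35 nt were cut from a gel and made into small RNA libraries. No matched RNA-seq was used here, so fragment counts reflect mRNA level and translation together and no translational efficiency was computed.

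The deposited table holds 49585 gene rows with Ensembl identifiers and 161 columns. Per the file headers, the authors gave counts of exon, intron and gene reads, each as unique reads (those that fit a single place) and total reads, along with expression values and RPKM. Checked on every row, the authors' expression value is a count equal to the unique exon reads plus the exon-exon reads that are not unique. The deposited RPKM values, scaled to exon length and mapped reads, were used only to recover the mapped reads, 7766936 to 11507207 per library. The aligner, the counter and the strand setting are not given in the sources used here, and GRCm38 and mm10 come from the submitters' processing notes. Per the file headers, the authors also deposited a test of PG against GC, called EDGE, with p-values, FDR-corrected p-values and a signed fold change; their values are named as the authors' where printed. A further 99 per-library columns were not used.

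The main measurement was the count of total exon reads. The planned design asked for all reads assigned to a gene or its coding sequence, which could mean exon or gene reads; exon reads were taken before any test was run, because introns held 63.6% to 68.7% of gene reads. Unique exon reads, expression values and gene reads were run as alternatives. In the introns, 10 genes held 67.9% of the reads, led by Peak1 with 12.4% and Sspn with 10.0%. Among these 10 were Rn18s-rs5 (9.01%) and n-R5-8s1 (4.34%), rows named for ribosomal RNA.

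Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with its minimum count of 10, TMM factors, glmQLFit and glmQLFTest) on 9124 of the 16855 genes with at least 1 exon read, with group as the only term and Benjamini-Hochberg adjusted p below 0.05 as the threshold. Positive log2 fold changes mean higher in PG. Standard errors were taken from the F statistic, CPM values are TMM-scaled and group values are mean ± SD with n = 3. The biological coefficient of variation was 19.5%. A rank or permutation test of single genes was not used, since 3 against 3 cannot give an exact permutation p under 0.10. Gene lists and marker lists (29 and 18, of which 41 had at least 3 measured members) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry. Members were also adjusted over each list alone. Biotypes were matched by symbol to a reference table of GRCm38.p6, which left 14151 rows unmatched; coordinates are those of the deposited table, shifted to count from 1.

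The lists described were shortened to 9 after the results were seen, and calcium handling and ribosomal proteins are given by their medians. The genes named in the text come from a rule that, like the gene and marker lists, the main test and the alternatives, was fixed before the data were examined: the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean is at least 1 CPM, without predicted names; up to 3 called members of each list described, or its 2 most abundant members where none was called and the list passed camera or is described as not moving; and Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Atp2a2, Pln, Fbxo32, Trim63, Nqo1, Cdkn1a, Fkbp5 and Dbp whatever their values. Manf, Rpl3l, Lars2, Tmem38b, Rn18s-rs5, genes named by their intron reads and the kidney and liver genes other than Kap fall outside it and were named after their values were seen.

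Tests were run on counts simulated from the real means, library sizes and dispersions for PG against GC, with 200 genes changed in each of 5 simulations of about 8862 tested genes. The quasi-likelihood test called 11.6% of genes changed 1.5-fold, 49.4% of those changed 2-fold and 92.3% of those changed 4-fold, and 6.36% of all calls were false. A list moved by 0.3 on the log2 scale was called in 5 of 5 simulations. Genes were drawn independently there, while the real mitochondrially encoded list had an estimated correlation of 0.895, so list calls with correlated members were not checked. So at this depth most 1.5-fold changes go undetected. Read counts are not corrected for PCR duplicates, so floors cover counting error only.

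Replicates were compared before averaging: within a group, chi-square per degree of freedom between libraries ran from 4.12 to 27.7, so no pair agreed within sampling noise. Alternatives were median-of-ratios and upper-quartile factors, library size alone, no filter, a minimum count of 50, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out mitochondrially encoded genes, haemoglobin genes or the 10 genes with the most reads, leaving out each library, the other count columns and an adjusted p of 0.10. Restricting the fit to protein-coding genes without Lars2 and Tmem38b was chosen after seeing the data.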

Results

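Ribosome-protected fragments, the stretches of mRNA that a ribosome shields from nuclease, were measured in the hearts of male mice that were 8 or 9 weeks old per the labels. The libraries fall into 2 groups of 3. The PG group was kept at 0.167 g, the gravity of the Moon, in a habitat cage turned at 31 rpm on a radius of 15 cm, and the GC group was the ground control at 1 g. Per the labels the ground mice lived in conditions like those aboard the space station, so PG and GC differ in flight as well as in gravity, and no flown group at 1 g was analysed here. The labels speak of ground mice for each mission but give no mission for a library, and they do not say that each library came from a different animal, so the p-values measure the spread between these samples.

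The table gave 2212473, 2348642 and 3196070 exon reads for GC replicates 1, 2 and 3 and 2741093, 2935343 and 2416699 for PG replicates 1, 2 and 3. A pair of genes, Lars2 and Tmem38b, took much of this depth, and whether their reads come from translated mRNA was not tested. Lars2 held 28.6% (PG replicate 3) to 37.0% (PG replicate 1) of a library's exon reads and Tmem38b 9.16% (PG replicate 1) to 23.9% (PG replicate 3). Their combined share ran from 45.5% to 52.5%, which left 1105514 to 1663167 exon reads per library for all other genes. PG replicate 3 stood apart in its Tmem38b share, since the other 5 libraries lay at or under 14.8%.

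The comparison of PG with GC asks how heart translation differs in mice kept at lunar gravity. Myh7, the slow beta isoform of the myosin heavy chain, was the gene with the smallest p, at 1118 ± 235 CPM in PG against 188 ± 24.9 in GC (SD, n = 3 each). That is a 5.95-fold higher level, with a log2 fold change of 2.57 ± 0.15 (SE) and an adjusted p of 6.13e-11 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Myom2, a protein of the sarcomere's M-band, rose from 417 ± 20.9 to 1042 ± 133 CPM. The skeletal actin gene Acta1 was 2.57-fold lower in PG, the cell-cycle inhibitor Cdkn1a 3.41-fold lower and Pdk4, a kinase that shuts down pyruvate dehydrogenase, 2.71-fold lower. In each of these 5 genes the 3 PG values lay on one side of the 3 GC values.

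Of 9124 genes tested, 53 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 23 higher and 30 lower in PG, and 953 had an unadjusted p under 0.05. Of the 53, 43 matched a protein-coding biotype. The calls include Rn18s-rs5, a pseudogene row named for ribosomal RNA, 1.85-fold lower in PG with an adjusted p of 0.000480 (edgeR). PG and GC values did not overlap in 16.3% of the tested genes, where chance gives 10% for 3 against 3. The median log2 fold change of all tested genes was 0.00 (-0.0017 before rounding), and it shifted to 0.06 with library size alone as the scaling, which also moved the share of called genes that were higher from 43.4% to 61.0%. The authors' deposited table has 31 genes past a false discovery rate of 0.05, 16 higher and 15 lower, and 21 of them were also called here. The count here rested on single libraries: it was 19 without GC replicate 2, 25 without PG replicate 1, 26 without PG replicate 2 and 102 without GC replicate 3.

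**Figure D1:**
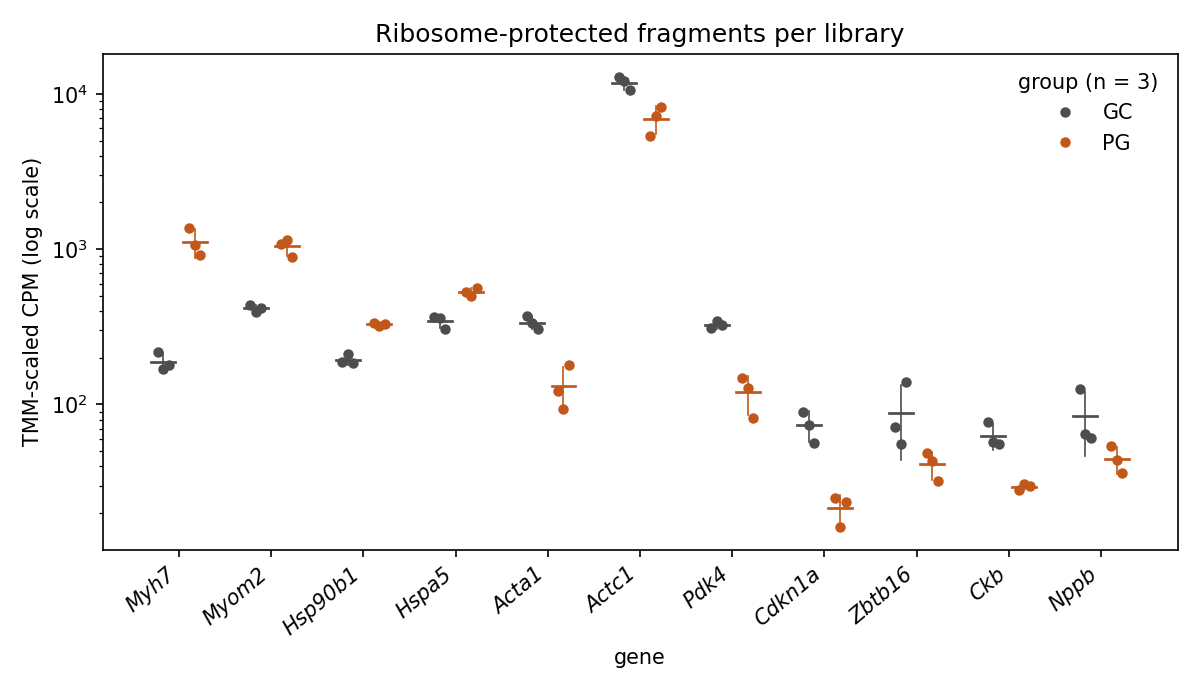
TMM-scaled CPM (vertical axis, log scale) of the genes on the horizontal axis in each library, grey for GC and orange for PG; points are libraries, horizontal bars group means and vertical bars 1 SD (n = 3). Myh7 lay at 169 to 216 CPM in GC and 912 to 1374 CPM in PG, while Nppb is shown as a gene that did not pass the test.

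Sarcomere genes went both ways. Of 35 measured members of that list, Myh7 and Myom2 rose, Acta1, Actc1 and Tnnc1 fell and 30 did not pass the test. Adjusted over the list alone, 5 were higher and 6 lower. Actc1, the main actin of the adult heart muscle, stood at 11784 ± 1155 CPM in GC and 6939 ± 1422 in PG (SD, n = 3), 1.70-fold lower with an adjusted p of 0.00477 (edgeR). Tnnc1, cardiac troponin C, was 1.40-fold lower. Actc1 missed the threshold without GC replicate 2 (edgeR adjusted p of 0.0812), and Tnnc1 missed it in 5 of the 6 fits that left out a library, with an adjusted p of up to 0.304. Myh6, the fast alpha myosin that lies beside Myh7, had a log2 fold change of -0.06 ± 0.12 (SE). Reads of actin and myosin paralogs can be split between genes by the counting, and 15.3% of Acta1 reads, 15.5% of Actc1 reads and 57.6% of Myh7 reads fitted a single place. On those unique reads the log2 fold changes were -1.08 for Acta1, -0.59 for Actc1 and 2.89 for Myh7, all still past the threshold. Mhrt, a noncoding transcript antisense to Myh7, was 2.57-fold lower in PG, but the files do not state whether counting used the strand. On its 79 unique reads Mhrt had a log2 fold change of -1.64 against -1.36 on all reads, with an adjusted p of 0.228 (edgeR), within a range of 0.000502 to 0.232 over the other settings, and 0.0550 without PG replicate 1. Myh7 spans positions 54970688 to 54994634 of chromosome 14 in the files' coordinates and Mhrt spans 54968678 to 54974349. GRCm38 and mm10 are the builds listed in the submitters' processing notes.

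Genes known to respond to cardiac load did not move in a shared direction. In the list of cardiac load and fetal genes, 17 were measured, Myh7 rose, Acta1 and Ankrd23 fell, and the other 14 did not pass; adjusted over the list alone, 3 were higher and 4 lower. Camera gave an adjusted p of 0.856 for the list, on the negative side, while its median was 0.01. Camera looks for a shared direction. Fry's mixed test, which counts changes either way, gave the list an unadjusted p of 8.11e-05, Myh7 included. The fall of Ankrd23 rests on reads that fit several places, since 2.57% of its reads were unique, 22 in GC and 25 in PG. The natriuretic peptide gene Nppb had a log2 fold change of -0.89 ± 0.23 (SE) and an adjusted p of 0.0685, and Nppa -0.14 ± 0.14 with 0.802 (edgeR). Ankrd1, a stretch-responsive repressor, had a log2 fold change of 0.52 ± 0.13 and an adjusted p of 0.0662. Nppb passed in 6 of 15 other settings and Ankrd1 in 7 of 15. The calcium pump gene Atp2a2 (-0.20 ± 0.11) and its inhibitor Pln (0.37 ± 0.12) did not pass, nor did the ubiquitin ligase genes Fbxo32 (0.65 ± 0.21) and Trim63 (0.11 ± 0.14). Outside the load list, Nqo1 (0.38 ± 0.19), Fkbp5 (-0.65 ± 0.27) and the clock gene Dbp (0.53 ± 0.41) did not pass either.

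Most nuclear genes of the respiratory chain had negative log2 fold changes and its mitochondrial genes positive ones. Both lists were called by camera with the preset correlation, but not with an estimated one or by fry. Among 78 measured nuclear-encoded genes of oxidative phosphorylation, 72 had a negative log2 fold change, with a median of -0.20, and camera with a preset correlation of 0.01 gave an adjusted p of 7.11e-07. With an estimated correlation the adjusted p was 0.733, and fry's was 0.260. No member passed over all genes tested in edgeR, where 26 were lower and 1 higher at an unadjusted p under 0.05, while DESeq2 called 7 lower and limma-voom 4 lower. Adjusted over the list alone, 15 were lower in edgeR. Its most abundant members, Atp5b (-0.12 ± 0.11) and Atp5a1 (-0.21 ± 0.12), are subunits of the ATP synthase. All 13 proteins encoded by mitochondrial DNA had positive log2 fold changes, with a median of 0.45 and a camera adjusted p of 0.000211. The adjusted p was 0.733 here too with an estimated correlation, and 0.397 with fry. Of these, mt-Nd3 (1.78-fold), mt-Nd2 (1.64-fold) and mt-Cytb (1.55-fold) rose, and 9 were higher when adjusted over the list alone. Of the reads of mt-Nd3, 4.22% were unique. The 3 genes missed the threshold in some fits that left out a library, with adjusted p-values (edgeR) of up to 0.102 for mt-Nd3, 0.162 for mt-Nd2 and 0.271 for mt-Cytb, each without GC replicate 2. Without PG replicate 3 the median of the mitochondrially encoded list was 0.26. Their share of the exon reads outside Lars2 and Tmem38b was 4.82% to 6.40% in GC and 6.64% to 9.10% in PG, highest in PG replicate 3. Mitochondria were spun out before digestion, so the mitochondrially encoded fragments come from what that step left. The amount left in each library was not measured directly, so uneven removal cannot be told apart from a change of these genes.

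Several genes for protein folding in the endoplasmic reticulum were higher in PG. Of 21 measured chaperone and unfolded-protein-response genes, 19 had positive log2 fold changes with a median of 0.40, 4 rose over all genes tested and 7 when adjusted over the list alone. The chaperone genes Hsp90b1 (327 ± 7.86 CPM in PG against 194 ± 14.3 in GC, SD, n = 3) and Hspa5 (530 ± 30.9 against 343 ± 34.2) rose 1.69-fold and 1.54-fold, and the disulfide isomerase gene Pdia6 rose 1.62-fold. The remaining member to rise was Manf, an endoplasmic reticulum stress protein. Hsp90b1 passed in every fit that left out a library, Hspa5 missed the threshold without GC replicate 2 (edgeR adjusted p of 0.0901), PG replicate 1 (0.0514) or PG replicate 2 (0.0519), and Pdia6 missed it in 5 of the 6 fits with an adjusted p of up to 0.276. Camera gave an adjusted p of 4.96e-06 for this list, and the adjusted p was 0.700 with an estimated correlation and 0.0470 with fry. The estimated correlation was 0.054 here. For the glucocorticoid list it was -0.018, below the preset 0.01, and camera's adjusted p still went from 0.0554 to 0.733. The higher values in that setting are therefore not a measure of correlation alone.

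**Figure D2:**
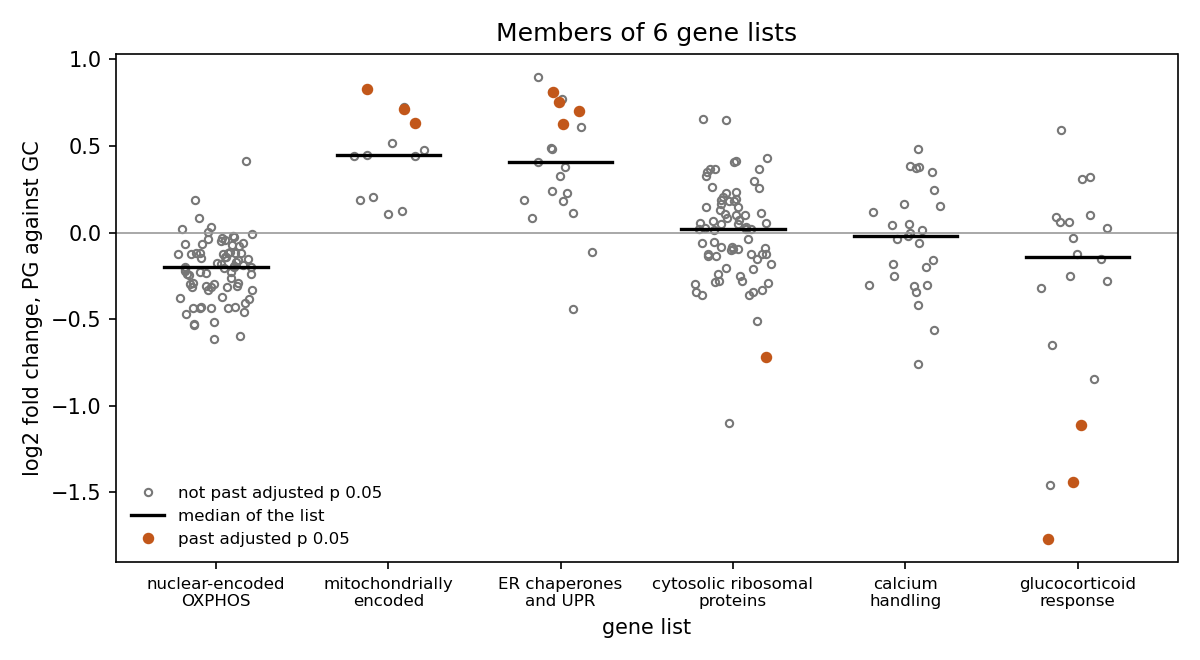
Log2 fold changes of PG against GC (vertical axis) for the measured members of 6 gene lists (horizontal axis); filled points passed an adjusted p of 0.05, open points did not and black bars are list medians. The median was -0.20 for nuclear-encoded oxidative phosphorylation genes, 0.45 for mitochondrially encoded proteins, 0.40 for endoplasmic reticulum chaperones and 0.02 for cytosolic ribosomal proteins.

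Several metabolic and hormone-responsive genes were lower in PG. Among 20 measured genes of the glucocorticoid list, Pdk4, Cdkn1a and the transcription factor gene Zbtb16 fell and none rose, with 1 higher and 4 lower when adjusted over the list alone; the list missed the camera threshold with an adjusted p of 0.0554. Pdk4 also belongs to fatty acid metabolism and Cdkn1a to the p53 response. In the fatty acid oxidation list of 38 genes, Pdk4 and the lipid-droplet gene Plin5 (1.89-fold) fell, and adjusted over the list alone 3 were higher and 9 lower. The creatine kinase genes Ckb (2.12-fold) and Ckm (1.56-fold) fell among 19 measured members of the creatine and energy buffering list, and 2 were lower when adjusted over the list alone. Zbtb16 and Ckm missed the threshold in 4 of the 6 fits that left out a library and Plin5 in 3, with adjusted p-values (edgeR) of up to 0.189 without GC replicate 3, 0.210 without GC replicate 2 and 0.117 without GC replicate 1. The 75 measured cytosolic ribosomal proteins had a median of 0.02, with camera on the negative side, and of these Rpl3l alone was called in edgeR. The 27 calcium-handling genes had a median of -0.02. None of these 27 was called in edgeR or limma-voom, 2 were called higher in DESeq2, and 2 were higher and 4 lower at an unadjusted p under 0.05 in edgeR.

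Among the other genes with large changes, Rundc3b had 0 reads in the 3 GC libraries and 81 reads in PG, at least 24.8-fold higher against a floor of 3 counts over the GC group. This bound was 15.2-fold without PG replicate 3 and 14.3-fold without GC replicate 3. H19, an imprinted noncoding RNA, was 2.62-fold higher. Sarnp, Capza1, Fpgt, Fbxl5 and the insulin-degrading enzyme gene Ide were also called higher, with log2 fold changes of 3.57, 2.55, 2.33, 0.97 and 0.96. Without GC replicate 1 the log2 fold change was 4.65 for Sarnp and 3.33 for Capza1. Only 19.8% of Sarnp reads and 9.88% of Capza1 reads were unique. Ano10, Yipf1 and Extl1 were called lower, with log2 fold changes of -1.22, -1.12 and -1.01. Each of these 8 genes missed the threshold in 3 to 5 of the 6 fits that left out a library, with the highest adjusted p for Fbxl5, 0.284 without PG replicate 1 (edgeR). Kap, an androgen-regulated kidney gene, stood at 18.0 ± 2.31 CPM in GC and 1.96 ± 2.13 in PG (SD, n = 3), 9.97-fold lower with an adjusted p of 0.00373 (edgeR). That fold rests on 5, 0 and 9 reads in PG replicates 1, 2 and 3, and the log2 fold change of -3.32 became -2.66 without PG replicate 2 and -4.39 without PG replicate 3. Beside it, 36 other kidney markers summed to 61.5 ± 16.8 CPM in GC and 29.6 ± 15.5 in PG. The summed liver markers stood at 101 ± 99.1 CPM in GC and 39.5 ± 22.1 in PG, and GC replicate 2 alone held 215 CPM. Both marker lists were chosen after the data were seen.

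No cell type marker list passed camera, while the ventricular cardiomyocyte list passed fry on the negative side with an adjusted p of 0.0470 (0.365 with camera). Of 12 measured cardiomyocyte markers Actc1, Ckm and Tnnc1 fell, none rose and 9 did not pass, and the list's adjusted p was 0.0652; adjusted over the list alone 1 was higher and 4 lower. The 38 lists that did not pass had camera adjusted p-values from 0.0528 (proteasome) to 0.941 (smooth muscle and pericyte). Of the 31 called genes that the naming rule gives, 12 passed in every fit that left out 1 library and 19 did not. Among the 12 were Myh7, Myom2, Rundc3b, Hsp90b1, H19, Pdk4, Cdkn1a, Acta1, Ankrd23, Kap and Ckb. Rundc3b could be tested in 5 of those fits.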

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

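The test of intron reads, and the tests on paralogs, skeletal muscle, thyroid hormone, mitochondrial rRNA and PG replicate 3 below, were chosen only after the results they address were seen, and the kidney and liver marker lists were written after Kap and other such genes had been seen. Intron reads by themselves enter no other comparison, though they are part of the gene reads run as an alternative and of the mitochondrial rRNA reads below. In edgeR's quasi-likelihood test on total intron reads, 1177 genes were tested and 31 passed, 26 lower and 5 higher in PG; 176 had an unadjusted p under 0.05. A signal above the ground controls appeared in those 5 genes: Tmem266 (log2 fold change 3.44), Gm14634 (2.31), Itga9 (1.92), Stk40 (2.59) and Rbbp8 (2.51). Itga9 had 501120 intron reads in GC and 1709296 in PG, while its 654 exon reads had a log2 fold change of -0.41 and an adjusted p of 0.459 (edgeR). Its share of a library's intron reads ran from 2.58% to 18.6%. Some of the 26 lower genes spread widely in GC, such as Grxcr1 (67.4 ± 69.8 CPM, SD, n = 3), and others did not, such as Tlk1 (4.89 ± 0.999). The intron test was not repeated with a library left out. Of the 31, 18 had too few exon reads to be tested on them. Of the other 13, 0 were called on exon reads in edgeR and 2 had an unadjusted p under 0.05, Mylk3 and Itga9, each with an exon fold change opposite in sign to that of its intron reads.

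Kap and other kidney-type and liver-type genes were lower in PG. Kidney RNA in the GC libraries remains open, its bound having been met: 36 other kidney markers with a mean under 10 CPM summed in GC to 2.08 times their PG level, and the lowest GC library (46.6 CPM) lay just above the highest PG library (46.0 CPM). That margin is thin, since without genes shared with the liver list the ratio was 1.88 and the libraries overlapped, and the most abundant members, Ass1, Hsd11b1 and Cyp2e1, are not restricted to the kidney. Some less abundant members differed more, with 26 reads in GC and 1 in PG for Miox, 18 and 1 for Slc12a1 and 13 and 1 for Kl. Others went the other way, such as Slc7a7 (17 and 36) and Cdh16 (7 and 15). Liver RNA in all GC libraries is argued against, because the liver markers, 2.55 times higher in GC on average, overlapped between the groups and stood high in GC replicate 2 alone. A biological fall of such transcripts in the heart was not tested separately and stays open.

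Most nuclear genes of the respiratory chain had negative and its mitochondrial genes positive log2 fold changes. Among 10000 random lists matched on exon length and mean CPM, the nuclear list's median of -0.20 lay at percentile 1.58. The central 95% of matched lists ran from -0.19 to -0.05 and so shared much of the shift. Random members were drawn independently, while the list's own members had an estimated correlation of 0.318. The random medians are therefore too narrow a yardstick, and this percentile cannot decide whether length or abundance is the whole cause. For the mitochondrially encoded genes, mitochondrial rRNA reads had a log2 fold change of 0.22 ± 0.13 (SE), between no change and the list's 0.45, so more mitochondrial ribosome material in PG cannot be told apart from a change of the mRNAs with these 3 libraries a group. Without PG replicate 3 their median was 0.26, between the bounds that would have made that library the source or excluded it. A difference between the gravity groups stays open for both, untested beyond this.

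Myh7 was higher while Acta1 and Actc1 were lower. Reads shared between paralogs are argued against, since on unique reads the smallest part of a log2 fold change kept by any of the 3 genes was 77.8%. Skeletal muscle in the PG libraries is argued against as a source of the higher Myh7. Skeletal muscle genes that the heart hardly uses summed to 0.744 times the GC level in PG. Their sums were 46.2 ± 6.35 CPM in GC and 34.4 ± 2.29 in PG (SD, n = 3). The lowest GC library (40.4 CPM) lay above the highest PG library (36.9 CPM). Skeletal muscle in the GC libraries would bear on the lower Acta1, and no bound was set for it. The planned skeletal muscle marker list had 5 measured members, all negative, with a median of -0.46. It missed the camera threshold with an adjusted p of 0.0554, and its only called member, Ckm, is also a cardiomyocyte marker. Single markers had few reads and went both ways, such as Mylpf (3 reads in GC and 7 in PG) and Myh2 (19 and 3). This explanation stays open. Lower thyroid hormone action in PG was not settled. The median of only 6 genes it represses, Myh7 left out, lay at percentile 98.8 of matched random lists, and 532 of 10000 such lists had a median as far from 0. The median of 16 genes it induces lay at percentile 30.2, which met the bound against it. Yet 62.5% of these were negative, and a median near 0 over members going both ways decides nothing, so this explanation stays open. A response to gravity or to flight was not tested and stays open.

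With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 53 genes and the highest other split 3, and it was the only 1 of the 10 with as many. For genes in one direction the real split gave 23 higher and 30 lower, each matched by no other split (1 of 10, counting the real split), where the highest other value was 2. For gene lists the real split called 3, and 7 of the 10 splits, the real one included, called as many, up to 8. The split of GC replicates 1 and 2 with PG replicate 3 against the rest gave the nuclear oxidative phosphorylation list an adjusted p of 9.95e-09, smaller than that of the real split, while the endoplasmic reticulum list had its smallest adjusted p in the real split.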

How the results depend on the processing

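Against 53 called genes (23 higher, 30 lower), the count was 181 (80, 101) without a filter, 103 (47, 56) with a minimum count of 50, 127 (54, 73) with DESeq2, 80 (49 lower) with limma-voom, 90 (38, 52) on unique exon reads, 88 (38, 50) on expression values and 111 at an adjusted p of 0.10; gene reads gave 13 higher, library size alone 16 lower and protein-coding genes without Lars2 and Tmem38b, chosen after seeing the data, 48 lower. Of the 53, DESeq2 also called 36, limma-voom 50, unique reads 44, the replicate block 22 and gene reads, which called 45 in all, 18. Leaving out 1 library gave 19 (GC replicate 2) to 102 (GC replicate 3) genes, 7 to 40 higher and 12 to 62 lower, with 25 without PG replicate 1 and 26 without PG replicate 2. Against 3 lists, library size alone called 6, a minimum count of 50 called 5, limma-voom 12, protein-coding genes 8 and an estimated correlation 0 (2 at an unadjusted p under 0.05), and leaving out 1 library 3 to 11; fry called 2, endoplasmic reticulum chaperones and ventricular cardiomyocyte markers. DESeq2 gives no list test. With the replicate number as a block 22 genes passed (11 higher, 11 lower). Deviations of same-numbered libraries from their group means correlated at -0.0083, -0.032 and -0.014. These values show no pairing across genes, but with 3 libraries a group they cannot exclude a shared litter or day. The labels do not say whether the numbers pair. Upper-quartile, median-of-ratios, haemoglobin, mitochondrial and top-gene settings kept each count within 1.5 times. Named genes kept direction and side of the threshold in 564 of 624 results from other settings and 187 of 263 that left out 1 library; Nppa turned positive on unique reads (0.071) and expression values (0.071) and ran from -0.32 to 0.028 when 1 library was left out, positive without GC replicate 1, and Myh6 from -0.15 to 0.049, positive without PG replicate 1, none past the threshold. Small list medians also turned: the load list to -0.052 with a minimum count of 50, and when 1 library was left out the load list ran from -0.18 (without PG replicate 3) to 0.12, fatty acid oxidation from -0.17 to 0.030 (without PG replicate 1) and creatine from -0.13 to 0.017 (without GC replicate 1). Fewer genes tested under a stricter filter and fewer libraries change the adjustment; otherwise the cause was not tested. Pseudocount alternatives were not run, since counts exist. Depth limits genes with few reads.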

Other observations

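No clock or glycolysis gene on the lists passed over all genes tested in edgeR, and neither list passed camera. At an unadjusted p under 0.05 in edgeR, 2 clock genes were higher and 1 lower, and 1 glycolysis gene was higher and 11 lower. DESeq2 called 1 clock gene higher, and 1 glycolysis gene higher and 2 lower, and limma-voom called 0 in both lists. In the circadian clock list of 17 measured genes, 2 were higher when adjusted over the list alone, Tef with a log2 fold change of 0.74 ± 0.20 (SE) and Nr1d2 with 0.79 ± 0.23, and neither passed over all genes (edgeR adjusted p of 0.0778 and 0.122). The clock list's camera adjusted p was 0.405. In the glycolysis list of 25 genes Pfkfb2 was higher (0.78 ± 0.20) and 3 were lower when adjusted over the list alone, Pfkl (-0.58), Pgam2 (-0.41) and Eno3 (-0.35), and the glycolysis list's camera adjusted p was 0.0554. The atrial light chain genes Myl7 (-0.66 ± 0.17) and Myl4 (-0.58 ± 0.15) were negative with adjusted p-values of 0.0852 and 0.0693. These genes were chosen after their values were seen.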
